A study of Mus musculus with 12 samples.

How the data were processed

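RNA came from left ventricles of wild-type mice 7 days after sham surgery or MI, with 6 libraries per group. Per the labels, total RNA was extracted with Magzol, and mRNA was enriched from it with oligo(dT). Strandedness is not stated. The submitters' notes for replicates 3 to 6 name Bowtie2, RSEM and DESeq2 without versions, those for replicates 1 and 2 name no tool, and all name the GRCm38 build. 1 table holds all 12 libraries and 18050 genes by Entrez ID. Its expected counts were deposited unscaled and are fractional, as RSEM estimates are. The authors also gave TPM, scaled to a common transcript total, and FPKM, scaled by gene length and fragment total. A separate deposited table gives FPKM for replicates 1 and 2 alone, for 17723 genes, of which 17029 are in both tables. Among genes of all 12 libraries, 425 are blank in replicates 1 and 2. No mitochondrially encoded gene is listed.

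Expected counts were rounded and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with the label set as covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The same test was run in each set alone, and the difference between sets was tested as an interaction of set and group. Because replicates 3 to 6 lay so close together, a further test summed them and counted them once per group, 3 against 3. This test, and the rule that a gene is called only when both tests call it, were chosen after the spread between replicates was seen. Levels are TMM-scaled CPM. Standard errors of log2 fold changes are the fold change over the square root of its F statistic. Gene symbols and positions came from RefSeq and GENCODE annotation of GRCm38, and 17995 of 18050 IDs were matched. Overlap with exons of other genes was computed for named genes and passed 10% for 14 of 115. Counting intervals and limits are exact at 95% and cover counting error only.

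The groups, comparisons, alternatives, 39 gene lists and the rule for named genes were fixed before the data were examined. Of the lists, 20 are biology lists and 19 are marker lists. They name 827 entries, of which 793 are in the table, 4 by a synonym. Lists with at least 5 tested members, 36 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Named genes are Peg3, the 5 largest rises and 5 largest falls among called genes with at least 10 CPM in the higher group and no overlap between groups, and the 3 members of each biology list with the smallest adjusted p. The rule adds from each biology list the most abundant member that did not pass or moved against the majority, and from each marker list the 2 most abundant members. It named 115 genes, of which 56 rose, 33 fell and 26 were not called. The values of 1 named gene are not reported here. Other genes are named where a list had few exceptions, and were chosen after their values were seen. Of 20 lists called by camera, 1 held with an estimated correlation, and with replicates 3 to 6 counted once 22 were called, none of which held with an estimated correlation (lowest adjusted p = 0.608).

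The tests were tested on simulated data with 200 changed genes and a coefficient of variation of 0.15 in replicates 1 and 2 and 0.025 in replicates 3 to 6. With libraries varying independently, the 12-library test recovered 98% of 2-fold and 99% of 4-fold changes with 1 false call. With replicates 3 to 6 of a group sharing 1 deviation it made 2903 false calls, 93.6% of its calls, and DESeq2 made 3135 and limma 3151. Requiring both tests left 10 false calls, 4.90%, and recovered 94% of 2-fold changes. The difference between sets was simulated only with libraries varying independently, not with a shared deviation. There the 12-library test made 273 false calls. Counting replicates 3 to 6 once made 0 but recovered only 4% of 2-fold and 96% of 4-fold differences. Camera called the changed list and 0 of 30 random lists, and fry called 3 of 30. Simulated genes varied independently of each other, while the estimated correlation within real lists reached 0.977. This check therefore could not show false calls from correlated members. The correlation was estimated from a fit without the interaction of set and group. A difference in effect between sets that members share therefore counts towards it. For oxidative phosphorylation, with the correlation of 0.977, the median difference was 1.43. How much of the correlation comes from this was not tested.

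Alternatives covered scaling (DESeq2 size factors, library size alone), the test (DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.01), filters, thresholds, the covariate, a replicate block, and leaving out each library. Replicate numbers did not pair sham with MI libraries, since correlations of same-numbered libraries ran from -0.185 to 0.0271, so the block is given only as an alternative. TPM was not tested, as counts carry the depth.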

Results

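RNA was sequenced from mouse left ventricles taken 7 days after surgery. The animals were wild type and had undergone either a sham operation or MI, read here as myocardial infarction, an ischaemic injury of the heart wall. Each group held 6 libraries, numbered 1 to 6. The submitters' processing notes part them into a set of replicates 1 and 2 and a set of replicates 3 to 6. Levels in CPM are given by set, while log2 fold changes and list medians are over 12 libraries unless a set is named. Expected counts summed to 15541334 and 16066681 in the sham libraries and 18546662 and 18602226 in the MI libraries of replicates 1 and 2. In replicates 3 to 6 they summed to between 9140353 and 9750764 for sham and between 14168412 and 14410783 for MI. The labels do not say that the libraries came from separate animals, so every p-value measures only the spread between these libraries, which may be technical.

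Group was the strongest structure in the data. Component 1 of the log2 CPM (TMM-scaled counts over library size) held 62.5% of the variance and placed all 6 sham libraries between -80.3 and -62.5 and all 6 MI libraries between 55.6 and 119. Component 2 held 24.2% and parted the sets, with replicates 1 and 2 between -87.5 and -41.5 and replicates 3 to 6 between 26.6 and 38.9. Muscle transcripts led the sham libraries: Myh6, the adult ventricular myosin heavy chain, took 2.47% of counts in sham replicates 1 and 2, and Mb, myoglobin, took 2.29% in sham replicates 3 to 6. Collagen transcripts led the MI libraries, where Col1a1 took 2.71% in replicates 1 and 2 and Col3a1 took 1.23% in replicates 3 to 6. Replicates 3 to 6 of a group lay far closer together than replicates 1 and 2. Their biological coefficient of variation was 0.0293 in sham and 0.0207 in MI, against 0.112 and 0.192 in replicates 1 and 2. A chi-square test between pairs put 7.96% to 12.1% of genes past an unadjusted p of 0.05 among MI 3 to 6 and 8.72% to 14.1% among sham 3 to 6, against 52.0% for the MI pair and 36.4% for the sham pair of replicates 1 and 2. After Benjamini-Hochberg adjustment 75 to 357 genes differed per pair there, a spread that repeat libraries of a single RNA could also show. The 12-library test takes the 4 libraries as separate samples, as the labels number them, and a second test counted them once per group.

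**Figure D1:**
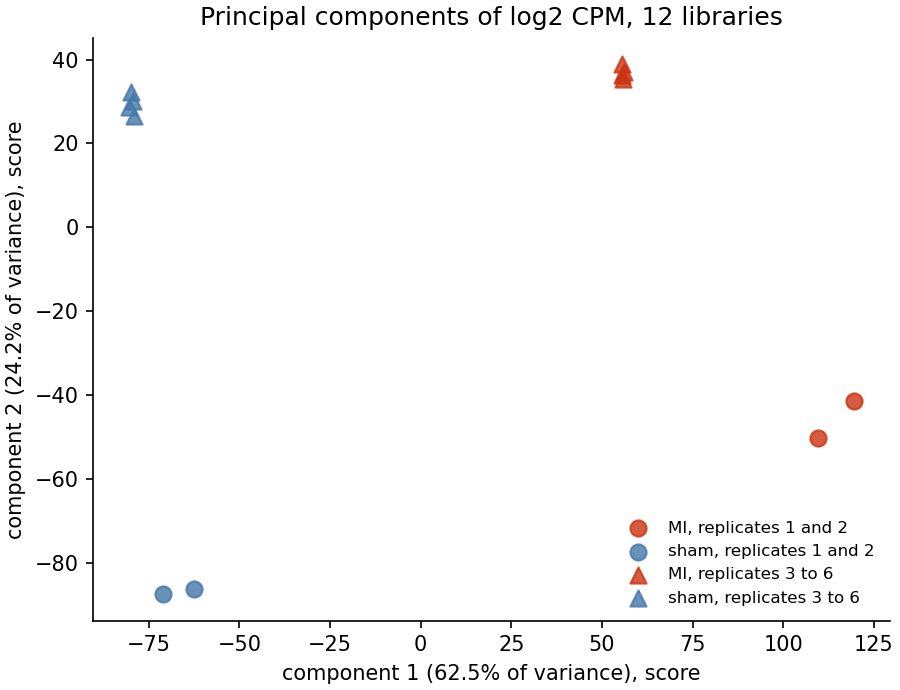
Scores of the 12 libraries on component 1 (x axis, 62.5% of variance) and component 2 (y axis, 24.2%) of log2 CPM, with blue for sham, red for MI, circles for replicates 1 and 2 and triangles for replicates 3 to 6. On component 1 sham libraries reach up to -62.5 and MI libraries start at 55.6.

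The series title asks about Pw1, the imprinted zinc-finger gene listed as Peg3 (gene ID 18616; GRCm38 chromosome 7, 6703892 to 6730462, minus strand). Peg3 rose after MI in both sets. Its level was 10.1 ± 1.68 CPM in sham and 30.97 ± 2.21 CPM in MI in replicates 1 and 2 (SD, n = 2 each), from 120 to 148 and 636 to 676 counts per library. In replicates 3 to 6 it was 17.6 ± 1.81 CPM in sham and 33.7 ± 2.04 CPM in MI (SD, n = 4 each), from 125 to 161 and 517 to 590 counts. The log2 fold change was 1.16 (SE 0.12, adjusted p = 3.26e-06) over 12 libraries and 1.36 (adjusted p = 0.00317) with replicates 3 to 6 counted once. Within the sets it was 1.60 and 0.98, and the difference between them passed the 12-library test (adjusted p = 0.00216) but not the test with replicates 3 to 6 counted once (adjusted p = 0.16). All 6 MI libraries lay above all 6 sham libraries (exact two-sided permutation test, p = 0.00216). The exact permutation p was 0.0286 in replicates 3 to 6. It was 0.333 in replicates 1 and 2 and 0.1 with replicates 3 to 6 counted once, each the smallest that design allows. No exon of another annotated gene overlapped the Peg3 exons.

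**Figure D2:**
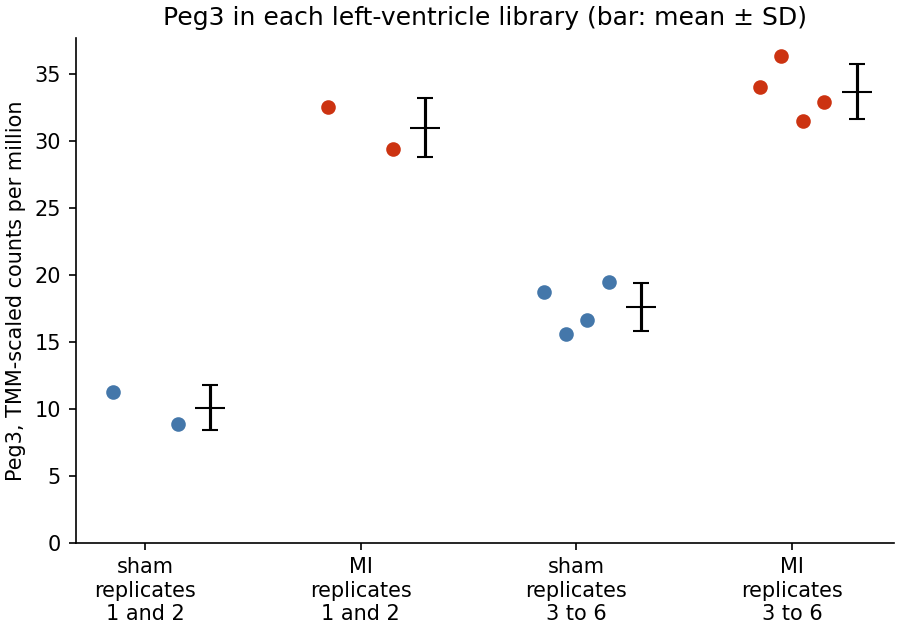
Peg3 in each library (y axis, TMM-scaled CPM) by group and set, with the mean and SD beside the points. MI libraries average 30.97 and 33.7 CPM against 10.1 and 17.6 CPM in sham.

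Among genes listed as imprinted, MI moved members both ways. Imprinting means expression from a single parental allele, but counts here are per gene, so allele use in these ventricles was not measured. Of 37 tested members of the list 12 rose, 16 fell and 9 did not pass. H13, an intramembrane protease gene, rose with a log2 fold change of 0.84 (SE 0.06). Blcap fell with -0.94 (SE 0.05), Cdkn1c, an inhibitor of cell-cycle kinases, with -1.52 (SE 0.09), and Gnas, the stimulatory G protein alpha subunit and the most abundant member moving against Peg3, with -0.65 (SE 0.07). Gnas lost its call with quantile-normalised FPKM, at 0.04. The list as a whole did not stand apart from other genes (camera, adjusted p = 0.966, and 0.962 with an estimated correlation). The median was 0.24 while the test pointed down. Adjusted over the list alone, 18 rose and 17 fell in the 12-library test, against 17 and 17 over all genes. Exons of other genes cover 30.6% of the Cdkn1c exons and 22.0% of the Gnas exons on the opposite strand. Whether counting used strand is not given in the sources used here, so both are uncertain.

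The comparison of MI with sham asks which genes respond to ischaemic injury by day 7. Genes of scar matrix rose, and genes of muscle excitation and mitochondrial fuel use fell. Over 12 libraries 5180 genes rose and 5186 fell out of 13654 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, label set as covariate). With replicates 3 to 6 counted once, 3934 rose and 4126 fell out of 13970. From here on, "rose" and "fell" are used only of genes called the same way by both tests, which were 3824 and 4055, of which 2316 and 2070 changed at least 2-fold. The series text gives 7614 changed genes, with no rule stated. Scaling by library size alone moved the median log2 fold change by 0.41 and the split to 7779 up and 3208 down. A log2(FPKM + 1) test moved it by 0.37, to 6883 up and 3055 down. Changes below that size therefore have a direction only relative to TMM scaling. MI 3 to 6 also held lung transcripts, at a summed 183 CPM, beside every change given here. MI 3 to 6 differed from sham 3 to 6 in beta-globin copies too, with Hbb-bs and Hbb-bt at 0.115% of beta-globin counts against 99.95%. A strain difference between these groups therefore stays open for every change that rests on replicates 3 to 6.

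The 5 largest rises by the naming rule were all in genes nearly silent in sham. Cthrc1, a secreted collagen-associated protein, had a log2 fold change of 11.60 (SE 0.26, adjusted p = 1.14e-11). It was counted 6 times in sham and 21671 times in MI in replicates 1 and 2, a ratio of 2268 (95% exact counting interval 1042 to 6181). In replicates 3 to 6 it was counted 2 and 24535 times, a ratio of 6203 (1717 to 51226). Such intervals cover counting error only. Col11a1, a fibrillar collagen, went from 0.211 ± 0.116 to 137 ± 2.13 CPM in replicates 3 to 6 (SD, n = 4). C1qtnf3, a secreted C1q/TNF-related protein, went from 0.119 ± 0.0956 to 224 ± 5.26 CPM there. Arg1, the arginase of alternatively activated macrophages, and Cemip, a hyaluronan-degrading protein, had log2 fold changes of 8.94 (SE 0.29) and 8.88 (SE 0.20). The 5 largest falls were Kcnv2 (-5.33), a modifier subunit of potassium channels, Ucp3 (-4.87), a mitochondrial uncoupling protein, Scn4a (-4.78), a sodium channel, Ces1d (-4.64), a carboxylesterase acting on lipids, and Efnb3 (-4.30), an ephrin ligand. Their standard errors were 0.19 to 0.34 and their adjusted p-values 1.39e-07 or lower. In replicates 1 and 2 Kcnv2 fell from 9.62 ± 0.606 to 0.189 ± 0.00534 CPM (SD, n = 2).

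Genes of the extracellular matrix rose almost without exception. Of 46 tested members 43 rose and 0 fell, with a median log2 fold change of 3.06. The other 3 were Col4a1 (1.59) and Col4a2 (1.47), both basement-membrane collagens, and Dcn (0.47), decorin, and each passed the 12-library test but not the other. Col8a1, a short-chain collagen, went from 52.0 ± 1.06 to 768 ± 12.5 CPM in replicates 3 to 6 (SD, n = 4) and from 52.5 ± 0.775 to 773 ± 19.9 CPM in replicates 1 and 2 (SD, n = 2). Col8a2 and Col5a2 rose with log2 fold changes of 6.80 (SE 0.11) and 4.61 (SE 0.09). The list stood apart from other genes (camera, adjusted p = 1.52e-19, and 0.00548 with an estimated correlation). With replicates 3 to 6 counted once the adjusted p was 1.52e-17, and 0.608 with an estimated correlation. In the 12-library test, when adjusted over the list alone, 46 rose, as over all genes.

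Genes that process and crosslink collagen moved with it, as 21 of 24 rose and 0 fell. P4ha3, a subunit of collagen prolyl hydroxylase, had a log2 fold change of 7.59 (SE 0.16), Adamts2, which trims procollagen, 3.22 (SE 0.09), and Crtap, a prolyl 3-hydroxylation partner, 1.57 (SE 0.05). P4ha2 (0.22, SE 0.14), Plod1 (0.42) and Pcolce2 (0.23) were not called. Of 25 matrix proteases and inhibitors 20 rose. Adam12 had a log2 fold change of 5.08 (SE 0.11) and Adamts12 3.66 (SE 0.14). Timp4, a metalloproteinase inhibitor abundant in heart, was the only member that fell (-4.29). Adamts5, Mmp3, Mmp9 and Mmp13 were not called. Camera gave adjusted p = 4.84e-10 for the crosslinking list and 6.31e-07 for the protease list. Neither held with an estimated correlation (adjusted p = 0.0825 and 0.393). Adjusted over the list alone, 22 crosslinking genes rose, and 21 protease genes rose and 1 fell.

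Of 33 genes of myofibroblast activation and TGF-beta signalling 24 rose. Ccn2, a matricellular TGF-beta target, had a log2 fold change of 3.51 (SE 0.08), Tgfb3 2.96 (SE 0.12) and Itgb5, an integrin that activates latent TGF-beta, 1.89 (SE 0.08). Myocd (-1.66) and Srf (-0.77), partners in smooth and cardiac muscle transcription, fell. Ltbp4 was level, with a log2 fold change of -0.07 (SE 0.09). Acta2, smooth muscle actin and the usual myofibroblast marker, passed the 12-library test (1.25, SE 0.21) but not the other, with 0.29 in replicates 1 and 2 and 1.77 in replicates 3 to 6. Markers of resting fibroblasts split, with 7 rising, 3 falling and 5 not called out of 15. Lsp1 (1.71, SE 0.10) and Tcf21 (1.57) rose, whereas Scara5 (-2.83, SE 0.06), Gsn (-1.76, SE 0.10) and Clec3b (-1.85) fell. Camera called the TGF-beta list (adjusted p = 1.75e-07, and 0.092 with an estimated correlation) and not the resting list (adjusted p = 0.868, and 0.962 with an estimated correlation). The median of the resting list was -0.14 while its test pointed up. In the 12-library test, when adjusted over the list alone, 26 TGF-beta genes rose and 2 fell, and 7 resting markers rose and 7 fell. Antisense exons cover 23.2% of the Ccn2 and 12.4% of the Tgfb3 exons, so both levels are uncertain.

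Transcripts of the heart muscle cell fell, as 22 of 25 sarcomere genes did. Tcap, titin-cap, went from 3055 ± 185 to 130 ± 3.65 CPM in replicates 1 and 2 (SD, n = 2) and from 2657 ± 165 to 494 ± 9.88 CPM in replicates 3 to 6 (SD, n = 4), and Myoz2, a Z-disc protein, had a log2 fold change of -2.47 (SE 0.30). Myl12b, a nonmuscle regulatory light chain whose exons overlap Myl12a, rose (0.64, SE 0.07), and Ttn (-0.49) and Des (-0.41) were not called. All 29 tested genes of calcium handling and ion channels fell, among them the potassium channels Kcnd2 (-2.66, SE 0.06) and Kcnj3 (-3.99, SE 0.15), the latter with 31.1% of its exons under an antisense transcript. Camera called both lists (adjusted p = 0.000355 and 1.15e-07), and neither held with an estimated correlation (0.634 and 0.462 as adjusted p). Adjusted over the list alone, 1 sarcomere gene rose and 22 fell, and 29 calcium and ion genes fell.

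Genes of mitochondrial fuel use fell. All 35 genes of fatty acid oxidation and all 45 of oxidative phosphorylation fell. So did all 32 of the tricarboxylic acid cycle and branched-chain amino acid breakdown. Their medians were -2.34, -2.20 and -2.11 over 12 libraries. In the same order they were -3.39, -3.22 and -3.07 in replicates 1 and 2. In replicates 3 to 6 they were -1.84, -1.70 and -1.54. Sarcomere and calcium and ion channel genes had medians of -1.71 and -1.99 over 12 libraries, so a fall particular to fuel use is not shown. Hadh, of the beta-oxidation spiral, went from 768 ± 9.60 to 90.4 ± 5.13 CPM in replicates 3 to 6 (SD, n = 4). Slc27a1, a fatty acid transporter, had a log2 fold change of -1.37 (SE 0.06). Ndufc2 of complex I had -1.64 (SE 0.10), Ndufa2 of complex I -1.71 (SE 0.11) and Atp5j of the ATP synthase -1.99 (SE 0.14). Antisense exons cover 11.5% of the Ndufa2 and 12.7% of the Atp5j exons, so both levels are uncertain. Mccc1 and Auh, of leucine breakdown, had -2.11 (SE 0.09) and -2.11 (SE 0.10), and Ppm1k, which activates branched-chain ketoacid breakdown, -2.28 (SE 0.11). Glycolysis was mixed, as 17 of 27 genes fell, 6 rose and 4 did not pass. Pfkfb1 fell (-3.26, SE 0.13), while the lactate exporter Slc16a3 (3.31, SE 0.15) and Pgam1 (0.74, SE 0.06) rose and Eno1 (0.60, SE 0.09) lost its call with replicates 3 to 6 counted once. Camera adjusted p-values were 1.17e-10, 2.96e-12, 1.63e-10 and 0.182 in that order. With an estimated correlation the first 3 became 0.462 each and glycolysis 0.758. With replicates 3 to 6 counted once glycolysis passed as lower (adjusted p = 0.047, and 0.707 with an estimated correlation). In the 12-library test, when adjusted over the list alone, 35, 45 and 32 fell, and 8 glycolysis genes rose and 17 fell.

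Genes of the fetal heart list, some of which stressed myocytes re-express, moved unevenly. The list median was 0.99 over 12 libraries, -0.31 in replicates 1 and 2 and 1.55 in replicates 3 to 6, and the difference between sets was not tested for the list. Of 18 tested 3 rose, 2 fell and 13 did not pass. Actn1 (2.61, SE 0.07), Mt2 (0.62) and Myl9 rose, the last with log2 fold changes of 2.01 in replicates 1 and 2 and 1.28 in replicates 3 to 6, and Tnnt1 (-2.68, SE 0.23) and Myl7 (-2.71) fell. Levels are of whole tissue, so the rises of Actn1, Mt2 and Myl9 are not tied to myocytes. Over 12 libraries alone 10 of the listed genes were up and 3 down, as also when adjusted over the list alone. Camera did not call the list (adjusted p = 0.153). Ankrd1, a stretch-responsive cofactor, and Nppa, atrial natriuretic peptide, parted the sets, as given with the comparison of the sets.

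Inflammatory genes rose. Of 28 cytokines and chemokines 24 rose and 0 fell, among them Spp1, osteopontin (7.62, SE 0.36), Cxcl16 (2.60, SE 0.19) and Cx3cl1 (2.03, SE 0.15). Cxcl12 (0.14, SE 0.08), Cxcl1, Cxcl9 and Csf1 were not called. Of 26 interferon-stimulated genes 24 rose, with Irf7, the master interferon regulator, going from 26.5 ± 2.59 to 201 ± 4.05 CPM in replicates 3 to 6 (SD, n = 4), and Xaf1 (2.27, SE 0.11) and Gbp2 (1.46, SE 0.09) beside it. Irf1 (0.38) and Cmpk2 (0.82) were not called. Of 27 complement and antigen presentation genes 21 rose and 0 fell. C3ar1, a complement receptor, had a log2 fold change of 3.09 (SE 0.23), Cfb 3.38 (SE 0.26) and Tap1 1.70 (SE 0.14), while C3 itself (0.57, SE 0.31) was at 1.88 in replicates 1 and 2 and -0.00 in replicates 3 to 6. Camera gave adjusted p = 2.78e-07, 7.02e-07 and 3.93e-05. None held with an estimated correlation (adjusted p = 0.393, 0.462 and 0.462). Adjusted over the list alone, 27, 26 and 23 rose. Overlapping exons cover 79.5% of Cfb, 18.8% of Spp1 and 18.3% of Cxcl16, so their levels are uncertain.

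Macrophage markers rose in 14 of 19 cases. Lyz2, lysozyme, went from 256 ± 9.28 to 2906 ± 703 CPM in replicates 1 and 2 (SD, n = 2) and from 565 ± 14.5 to 2510 ± 43.2 CPM in replicates 3 to 6 (SD, n = 4), and Gpnmb, a marker of lipid-handling macrophages, had a log2 fold change of 7.25 (SE 0.58). Cd163, of resident macrophages, fell (-2.80), and Mrc1, Ly6c2, Lyve1 and Timd4 were not called. Of 11 T and NK cell markers 6 rose, among them the granzyme Gzma (2.91, SE 0.28) and Il2rb (2.27, SE 0.31). Of 6 neutrophil markers 3 rose, Csf3r (2.16, SE 0.43), Cxcr2 and Mmp8, and S100a9 (0.89, SE 0.46) was not called. Of 7 B cell markers only Cd22 (3.32, SE 0.40) rose, and Cd79b (0.57, SE 0.28) was not called. Of 11 dendritic and mast cell markers Flt3, Itgax (5.51 and 3.25 in replicates 1 and 2 and 3 to 6), Siglech and Kit rose, and Zbtb46 (-0.19, SE 0.08) was not called. Camera called the macrophage (adjusted p = 0.000354) and T and NK lists (adjusted p = 0.00655), neither with an estimated correlation (adjusted p = 0.462 for both). Neutrophils (adjusted p = 0.114), B cells (0.701) and dendritic and mast cells (0.563) were not called, and neutrophils passed with replicates 3 to 6 counted once (adjusted p = 0.0442, and 0.678 with an estimated correlation). In the 12-library test, when adjusted over the list alone, 15 macrophage markers rose and 2 fell, and 10 T and NK, 4 neutrophil, 2 B and 5 dendritic and mast markers rose.

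Cell division genes rose in 23 of 31 cases. Ccnb1, cyclin B1, had a log2 fold change of 2.79 (SE 0.21), Tyms, thymidylate synthase, 1.72 (SE 0.13) and Mcm6, of the replication helicase, 1.34 (SE 0.09). Cenpf fell (-0.96), and Ccnd1, cyclin D1 (-0.24, SE 0.18), was among 7 not called. Ccnd1 lay at 109 to 116 CPM in sham and 50.5 to 56.4 CPM in MI of replicates 1 and 2. In replicates 3 to 6 it lay at 82.5 to 96.2 and 94.7 to 104 CPM, so the combined value hides a difference between sets. Antisense exons cover 23.4% of Ccnd1, so its level is uncertain. Of 24 endoplasmic reticulum stress genes 14 rose. The disulfide isomerases Pdia4 (1.55, SE 0.07) and Pdia3 (1.34, SE 0.09) rose, and Herpud1 (-1.86, SE 0.06) and Atf6 (-0.54) fell. Canx, calnexin (-0.13, SE 0.06), was not called. Hypoxia genes split, with Hmox1, haem oxygenase (2.27, SE 0.08), P4ha1 (1.14, SE 0.08) and Car9 (2.26) rising, 6 falling and 9 not called out of 18. Egln1, the oxygen-sensing prolyl hydroxylase, fell (-2.21, SE 0.16), and Vegfa (-0.49, SE 0.26) was not called. Of 27 angiogenesis genes 6 rose and 5 fell. Hgf (3.47, SE 0.24) and Pdgfc (2.62, SE 0.19) rose and Vegfb fell from 594 ± 16.6 to 57.6 ± 10.9 CPM in replicates 1 and 2 (SD, n = 2). In replicates 3 to 6 Vegfb fell less, with sham libraries at 354 to 389 CPM and MI libraries at 91.8 to 96.5 CPM. Camera called cell division (adjusted p = 2.15e-06) and endoplasmic reticulum stress (adjusted p = 0.00625), neither with an estimated correlation (adjusted p = 0.462 for both). Hypoxia (adjusted p = 0.581) and angiogenesis (0.739) were not called. Adjusted over the list alone, 27 division genes rose and 1 fell, 18 stress genes rose and 4 fell, 4 hypoxia genes rose and 8 fell, and 8 angiogenesis genes rose and 5 fell.

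Vessel wall markers moved both ways. Of 14 markers of blood vessel endothelium 5 fell, Tek, Tie1, Egfl7, Fabp4 (-1.90, SE 0.15) and Ly6c1, and Eng, endoglin, was level at 190 ± 8.41 and 200 ± 9.18 CPM in replicates 3 to 6 (SD, n = 4). The falls of Tek (-0.31), Tie1 (-0.40) and Egfl7 (-0.33) are smaller than the scaling shift, as is the list median of -0.13. Of 13 smooth muscle and pericyte markers 4 rose and 6 fell, with the pericyte gene Rgs5 at -1.01 (SE 0.12) and Cnn1 at 2.46. Of 10 mesothelium and epicardium markers 7 rose, among them Aldh1a2, which makes retinoic acid (1.60, SE 0.12), whereas Upk3b (-0.20, SE 0.43) was not called. Of 7 cartilage and bone markers 6 rose, including Comp, a cartilage matrix protein (5.06, SE 0.48), and Alpl fell (-0.93, SE 0.28). Comp also belongs to the matrix list. Camera called the mesothelial (adjusted p = 0.0271) and cartilage lists (adjusted p = 0.00866), neither with an estimated correlation (adjusted p = 0.462 for both). Blood vessel endothelium (adjusted p = 0.328) and smooth muscle (0.84) were not called, and the mesothelial call was lost without MI replicate 2 (adjusted p = 0.0645). In the 12-library test, when adjusted over the list alone, 4 endothelial markers fell, 6 smooth muscle markers rose and 7 fell, 8 mesothelial markers rose, and 6 cartilage markers rose and 1 fell.

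Markers of fat cells and of other tissues around the ventricle were also measured. Of 5 tested fat markers 4 fell, Plin4, a lipid droplet coat protein (-1.90, SE 0.24), Cidea, Fabp4 and Lipe, and Cfd was not called. Fabp4 is also on the endothelial list, and Lipe and Plin4 are also expressed by muscle. Of 8 lymphatic markers Pdpn and Fgl2 (1.19, SE 0.13) rose, Prox1 and Ccl21a (-0.69, SE 0.11) fell and 4 were not called. Of 10 Schwann cell and neuron markers S100b, Ncam1 (3.26, SE 0.12), Tubb3 and Npy (6.23) rose, Dbh, which makes noradrenaline, fell (-1.75), and Prnp (0.18, SE 0.09) was among 5 not called. Of 8 atrial markers Dkk3 (4.01) rose, Myl7, Tbx5 and Kcna5 fell, and Nppa, Myl4, Nr2f2 and Myl1 were not called. Of 7 skeletal muscle markers Tnnt3 (2.37) and Pvalb (3.61) rose, Ckm, muscle creatine kinase also made by heart, fell (-3.01, SE 0.51), and 4 including Mybpc2 were not called. Antisense exons cover 15.5% of Ckm, so its level is uncertain. Camera called the fat list as lower (adjusted p = 0.0269, and 0.462 with an estimated correlation). It did not call the lymphatic (adjusted p = 0.796), Schwann cell and neuron (0.613), atrial (0.752) or skeletal muscle lists (0.32). The Schwann cell and neuron median was -0.14 while the test pointed up. The same held for the dendritic and mast cell list (-0.13) and the angiogenesis list (-0.07). Of the RNA quality list only Snhg11 was tested, with a log2 fold change of -0.97 in replicates 3 to 6 and not called, with 0 counts in replicates 1 and 2, and of 13 mitochondrially encoded genes 0 were in the table. Adjusted over the list alone, 5 fat markers fell, 3 lymphatic markers rose and 4 fell, 4 Schwann cell and neuron markers rose and 3 fell, 2 atrial markers rose and 4 fell, and 3 skeletal muscle markers rose and 1 fell.

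**Figure D3:**
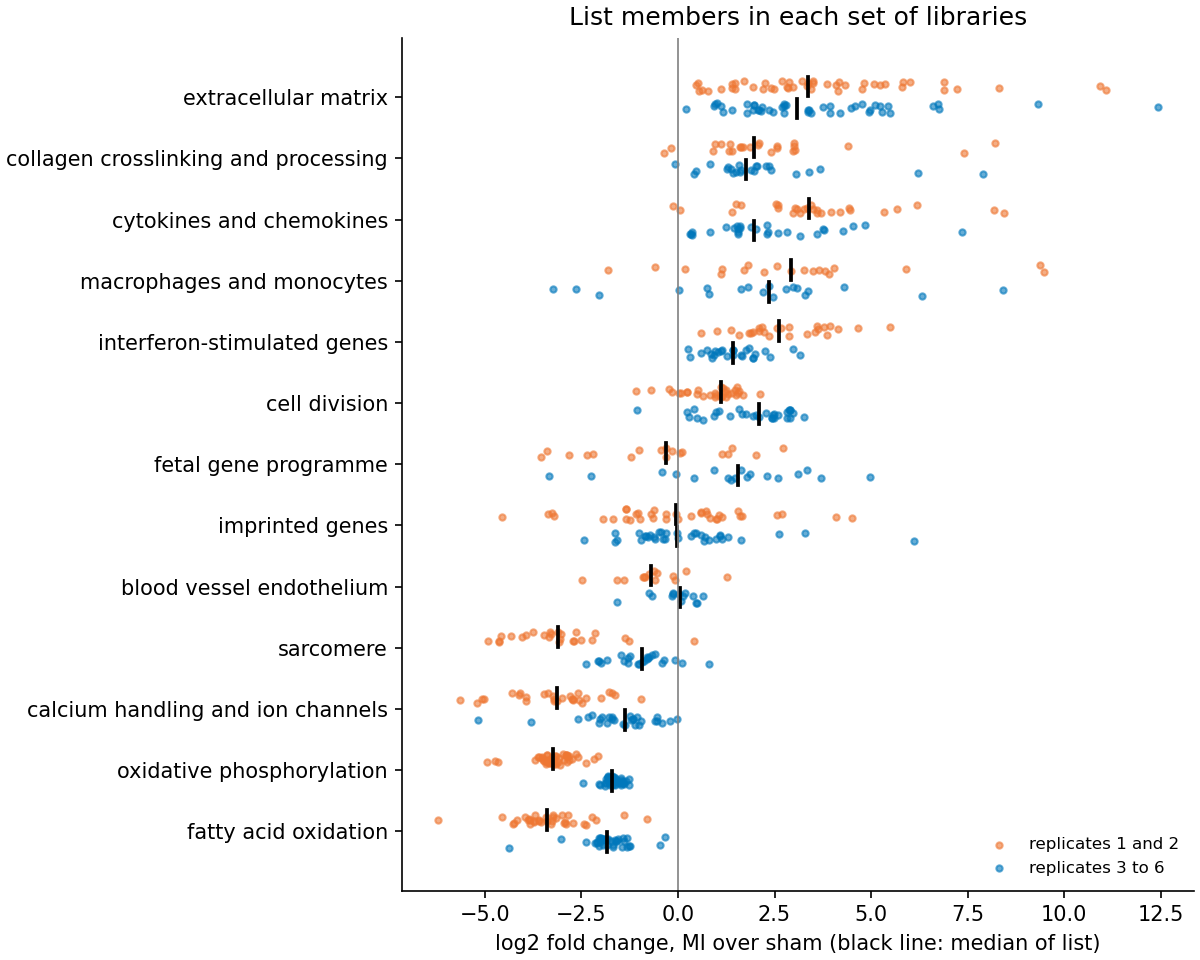
Log2 fold change of MI over sham (x axis) for each member of 13 gene lists (y axis), in orange for replicates 1 and 2 and blue for replicates 3 to 6, with a black line at the list median. Matrix genes lie to the right in both sets (medians 3.35 and 3.08), and oxidative phosphorylation genes lie to the left (-3.22 and -1.70).

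Comparing the sets asks how far the response repeats in a separate set of libraries. The median log2 fold change of matrix genes was 3.35 in replicates 1 and 2 and 3.08 in replicates 3 to 6. The sarcomere median was -3.10 and -0.93 in the same order, and that of calcium handling and ion channels -3.12 and -1.38. The difference between sets was tested for genes, not for lists. In replicates 1 and 2 alone 4804 genes were up and 4635 down, and in replicates 3 to 6 alone 5828 and 5453. Across 13406 genes tested in both, log2 fold changes correlated with Pearson's r of 0.789 and Spearman's rho of 0.811, without a p, since genes are not independent replicates. Of genes called in replicates 3 to 6, 87.7% had the same sign in replicates 1 and 2. Up in both were 3815 genes (1910 for independent lists) and down in both 3796 (1800), while 469 were called in opposite directions.

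Several genes of stressed myocytes parted the sets. Nppa stood at 2136 ± 499 in sham and 5336 ± 2309 CPM in MI of replicates 1 and 2 (SD, n = 2), and at 166 ± 15.0 and 4997 ± 65.0 CPM in replicates 3 to 6 (SD, n = 4). Myh7, the fetal myosin heavy chain, stood at 2829 ± 231 in sham and 564 ± 422 CPM in MI of replicates 1 and 2, and at 94.1 ± 4.14 in sham and 1184 ± 23.4 CPM in MI of replicates 3 to 6. Ankrd1 had log2 fold changes of -1.21 and 2.29, and Nppb, a natriuretic peptide, 0.11 and 3.12. Myh7 and Nppb were chosen for mention after their values were seen. With replicates 3 to 6 counted once, the difference between sets passed the test for Nppa (adjusted p = 0.0264), Myh7 (0.0248) and Ankrd1 (0.0257) but not for Nppb (0.0772). In that test each group of replicates 3 to 6 is 1 column, so the spread it measures comes from replicates 1 and 2 alone. By that test 1451 genes differed between sets. Over 12 libraries 7503 did, a count that takes the small spread of replicates 3 to 6 as that of separate animals. Antisense exons cover 61.5% of Nppa, so its level is uncertain.

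Transcripts of other tissues also parted the libraries. Lung markers summed to 183 ± 2.10 CPM in MI 3 to 6 (SD, n = 4), against 1.65 ± 0.464 in sham 3 to 6, 0.824 ± 0.197 in sham 1 and 2 and 3.68 ± 0.171 in MI 1 and 2. Of 2 lung markers past the count filter Ager rose (4.03, SE 0.23) and Rtkn2 (1.58, SE 0.27) was not called, too few for a list test. None of 7 tested red blood cell markers was called in both tests, and camera did not call the list (adjusted p = 0.32). Without MI replicate 1 it was called as lower (adjusted p = 0.0357). Hba-a1, an alpha-globin, had a log2 fold change of -0.02 (SE 0.39). Hba-a2, the other alpha-globin, stood at 809 ± 58.8 CPM in sham and 28.0 ± 8.72 CPM in MI of replicates 3 to 6, and at 118 ± 29.3 and 168 ± 188 CPM in replicates 1 and 2. Hba-a2 was chosen for mention after its values were seen. Hbb-bs, an adult beta-globin, stood at 2514 ± 64.1 CPM in sham and 1.77 ± 0.814 CPM in MI of replicates 3 to 6, and at 1337 ± 275 and 1997 ± 2258 CPM in replicates 1 and 2. Y-linked genes summed to between 6.67 and 10.7 CPM in replicates 1 and 2 and between 269 and 317 CPM in replicates 3 to 6, in sham and MI alike. In replicates 1 and 2 nearly all of the sum came from Uty and Eif2s3y, as Ddx3y and Kdm5d had at most 1 count per group. Acute-stress genes, which also respond to handling, rose in 10 of 14 cases, with Jun at 0.33 (SE 0.05) and Dusp1 at -0.44 (SE 0.09), the latter not called. Camera called that list (adjusted p = 0.0128, and 0.462 with an estimated correlation). In the 12-library test, when adjusted over the list alone, 2 lung markers rose, 3 red blood cell markers fell, and 10 acute-stress genes rose and 1 fell.

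**Figure D4:**
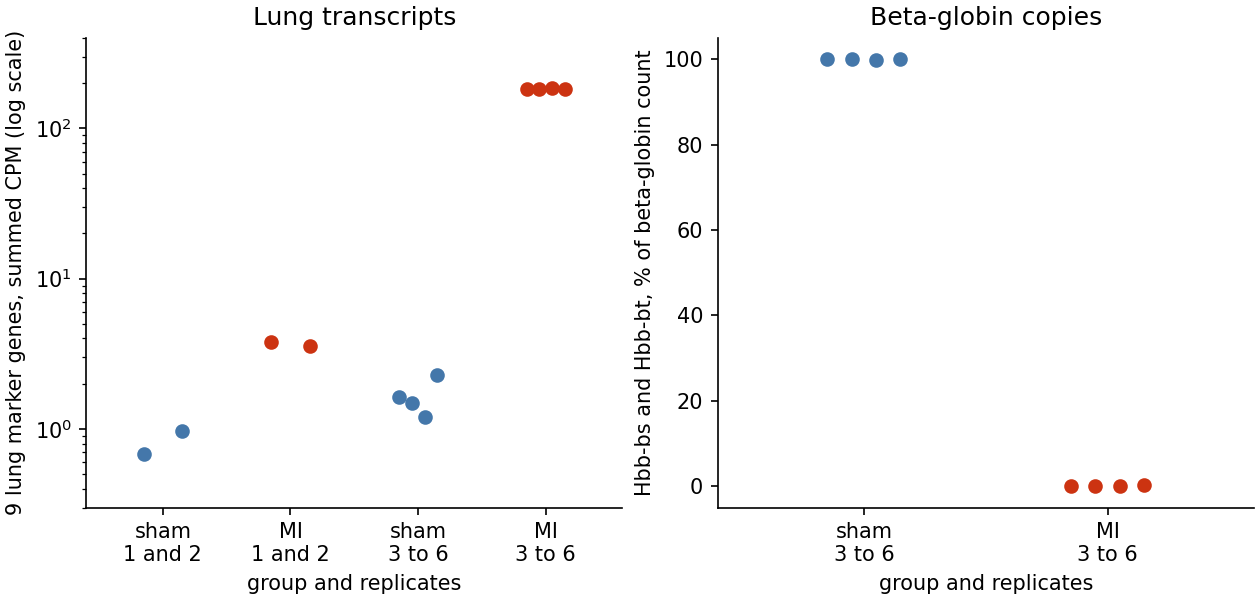
Left, summed CPM of the lung marker list (y axis, log scale) in each library by group and set. Right, the percentage of beta-globin counts assigned to Hbb-bs and Hbb-bt in replicates 3 to 6. MI 3 to 6 hold 183 CPM of lung transcripts, and their share of Hbb-bs and Hbb-bt is 0.115% against 99.95% in sham.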

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

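The tests of the coefficient of variation, lung transcripts, sham levels of fetal genes, the globin split, genes over 64-fold apart, myocyte share and sex were chosen only after the result was seen.

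Replicates 3 to 6 of each group gave nearly the same counts, with a biological coefficient of variation of at most 0.0293 against 0.112 and 0.192 in replicates 1 and 2. Lower depth is argued against, since thinning replicates 1 and 2 to that depth left at least 29.1% of genes past an unadjusted p of 0.05, above the 14.1% of the widest pair of replicates 3 to 6. Repeat measurement of 1 RNA per group stays open, as the coefficient of 0.0293 is the pattern itself. The acute-stress list, with a median variance of at most 1.30 times its counting expectation, cannot decide it, since genes in general lay as close. Pairs over all genes gave 1.16 to 1.66, but these were divided by the median that counting noise gives. The figures are therefore on different scales. Pooled animals stay open too, and the design gives no biological explanation to test. The lung list summed to between 181 and 186 CPM in every MI library of replicates 3 to 6, against at most 2.29 CPM in sham. Such a level lung signal argues against separately collected hearts for MI 3 to 6. It does not tell repeat libraries from a pool, and sham 3 to 6 held no such signal to judge by.

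Lung transcripts and a change of globin copies mark MI 3 to 6, where Sftpc reached 114 CPM, the share of Hbb-bs and Hbb-bt was 0.115% against 99.95% in sham, and Hba-a2 was 28.0 against 809 CPM. Infarction by itself is argued against, since the lung list summed to at most 3.80 CPM in MI 1 and 2. Lung tissue or RNA in the samples may account for the lung part, as 8 listed lung genes were higher in every MI than in every sham library of replicates 3 to 6, including Sftpc 114, Sftpa1 27.7 and Sftpb 13.6 CPM. A split of reads between beta-globin copies, made alike in both groups, would give sham and MI 3 to 6 similar shares. Instead Hbb-bs and Hbb-bt held at least 99.88% in each sham and at most 0.194% in each MI library, 99.8 percentage points apart in the mean. The values argue only against a split made alike. Reads assigned differently in sham and MI were not tested, so read assignment as a cause stays open. A strain difference between sham and MI 3 to 6 stays open. Its first test found 0 genes but could not find its own pattern, because Hbb-bs at 1.77 CPM is above the 0.1 CPM limit set for absence. A later test found 7 genes over 64-fold apart in replicates 3 to 6 alone against 3 in the mirrored pattern. That gap was too small for the 5 asked. The 7 include Hbb-bs and Hbb-bt, which raised the question, so the count partly repeats the pattern. The others were Zfp990, Klra8, Ceacam2, Rpl34-ps1 and Gm7429. Hbb-b1 and Hbb-b2 are blank in replicates 1 and 2 and could not enter. The count therefore decides nothing.

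Nppa, Ankrd1 and Myh7 differed between the sets, while Nppb, with a difference of 2.94, did not pass (adjusted p = 0.0772). A lower share of myocyte RNA in MI 1 and 2 is argued against as the whole cause for Nppa and Myh7, since their sham levels were at least 9.82 times as high in replicates 1 and 2 as in replicates 3 to 6. It stays open for Nppb and Ankrd1, since 2.94 lies above 2.67, the 95th percentile of 166 other myocyte genes, but below their highest, 3.90, and the genes were picked because they differed. Sex cannot be told apart from the set, because Y-linked levels of replicates 3 to 6 were at least 25.1 times those of replicates 1 and 2, and it could contribute. Ddx3y and Kdm5d had at most 1 count per group in replicates 1 and 2. In replicates 3 to 6 Ddx3y had 4518 counts in sham and 7676 in MI, and Kdm5d 550 and 1309. Female animals in replicates 1 and 2 and male animals in replicates 3 to 6 would give this pattern. Infarct size and sampled region were not tested and stay open.

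A library stood far from the rest of its group, by Dixon's ratio of gap to range, in 35 of 232 groups of 6, against 11.6 by chance. MI 2 accounts for 17, MI 1 for 10, and sham 1 and sham 2 for 4 each, all from the set of replicates 1 and 2. With 4 near-identical libraries in each group, the ratio is bound to point at the other pair. MI 2 was highest for Scn4a (0.850), Adamts5 (0.764), Pgam1 (0.721), Spp1 (0.838), Cxcl16 (0.902), C3ar1 (0.742), Cfb (0.786), C3 (0.723), Pdia3 (0.834), Lyz2 (0.841), Gpnmb (0.896), Csf3r (0.874), Il2rb (0.686), Cd22 (0.909), Itgax (0.877) and Aldh1a2 (0.679), and lowest for Cxcl12 (0.655). MI 1 was highest for Adamts12 (0.654), Gsn (0.713), Gbp2 (0.651), P4ha1 (0.923), Ccl21a (0.679), Hba-a1 (0.804), Hbb-bs (0.889) and Comp (0.649), and lowest for Efnb3 (0.785) and S100a9 (0.784). Sham 1 was out for Cthrc1 (0.673), Efnb3 (0.642), Egln1 (0.711) and Herpud1 (0.676), and sham 2 for Eno1 (0.672), Il2rb (0.824), Myl1 (0.936) and Hba-a1 (0.892).

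The MI effect differed between sets by the interaction test with replicates 3 to 6 counted once for 12 named genes. That test measures no spread within replicates 3 to 6. As log2 fold change in replicates 3 to 6 minus that in replicates 1 and 2, the difference was 1.74 for Ucp3, -1.36 for Adamts5, 2.13 for Tcap, 3.44 for Ankrd1, 1.25 for Ccnd1, 1.37 for Vegfb, 1.41 for Acta2, 1.53 for Plin4, 3.59 for Nppa, 3.28 for Ckm, -11.05 for Hbb-bs and 1.84 for Alpl.

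Transcripts outside the tested genes were present in MI 3 to 6 above the sham level. They were Sftpa1 (27.7 CPM), Sftpb (13.6), Sftpc (114), Sftpd (4.15), Cldn18 (5.37), Lamp3 (4.64), Hbb-b1 (1347) and Hbb-b2 (260.4).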

How the results depend on the processing

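The count with replicates 3 to 6 summed and counted once, the separate table of replicates 1 and 2, and the tests of named genes within each set were chosen after the data were seen. Counts over 12 libraries stayed within 1.5 times of 5180 up and 5186 down under DESeq2 size factors (5222 and 5134), the DESeq2 Wald test (5273 and 5185), no filter (5937 and 5221), at least 10 CPM (3988 and 3902), an adjusted p under 0.01 (4529 and 4606), no set covariate (3844 and 3856), a replicate block (4750 and 4749) and replicates 3 to 6 counted once (3934 and 4126). Of 8060 genes called in the last, 7879 were also called the same way over 12 libraries. Library size scaling alone gave 7779 up and 3208 down, and in replicates 3 to 6 alone 3598 down. Its own shift of the median by 0.41 shows the cause. In limma, genes down numbered 3055, 3042 and 3034 with pseudocounts of 1, 0.1 and 0.01 and 3046 without trend or robust fitting over 12 libraries. The same order gave 3343, 3329, 3327 and 3320 in replicates 3 to 6 and 2986, 2983, 2980 and 2963 in replicates 1 and 2, where the separate table gave 3004. Median centring of the same FPKM gave 5103, 5703 and 4427 down in those groups of libraries, and quantile normalisation 4918, 5366 and 4173, which shows the scaling shift as the cause. A minimum of 2-fold left 2478 up and 2206 down over 12 libraries, 2314 up and 1843 down in replicates 3 to 6, and 2880 down in replicates 1 and 2, as a stricter threshold must. Differences between sets fell from 7503 to 1451 genes with replicates 3 to 6 counted once, a test with fewer samples. Of 36 lists tested, 20 were called, 1 with an estimated correlation and 32 with fry, which asks another question.

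Leaving out 1 library gave 5079 to 5337 up and 4959 to 5225 down over 12 libraries, 5704 to 5851 and 5357 to 5439 in replicates 3 to 6, and 3396 to 4663 and 3751 to 4591 in replicates 1 and 2, where the lone library left in a group is assumed to vary like the other group. It gave 19 to 21 lists and a Peg3 log2 fold change of 1.06 to 1.23. Without MI replicate 2 the mesothelial list was lost (adjusted p = 0.0645), and without MI replicate 1 the red blood cell list was gained (0.0357). Over 12 libraries, leaving out 1 library brought a call to P4ha2 (MI 2), Ankrd1 (sham 2, MI 1 or MI 2), Cxcl12 (sham 1 or MI 2), Canx (sham 2 or MI 2), S100a9 (MI 2), Cd79b (MI 4), Prnp (sham 2 or MI 2) and Mybpc2 (MI 2), and ended that of Hbb-bs (MI 4 or MI 6) and, in 8 cases, of Zbtb46. Counting replicates 3 to 6 once ended the calls of Eno1, Zbtb46, Acta2, Nppa, Rtkn2, Hbb-bs and Dusp1. Of 115 named genes 114 kept their direction and side of the threshold with DESeq2 size factors and 101 with library size scaling, as did 107 of the 114 tested with replicates 3 to 6 counted once. Zbtb46, at -0.19, turned to 0.22 with library size scaling, to 0.22, 0.26 and 0.26 with the pseudocounts and to 0.22 without trend or robust fitting, a size below the scaling shift. Peg3 stayed called under every alternative run over 12 libraries, from 0.61 (quantile-normalised FPKM) to 1.58. Depth limits genes with few sham counts, such as Cthrc1 with 2 in replicates 3 to 6, to ratios with wide counting intervals.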

Other observations

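The gene families given here were formed after the data were seen, by the start of the symbol, and their tests were chosen then, while the tests of other sample splits were chosen before. Mitochondrial ribosomal proteins, which build the ribosome inside mitochondria, fell without exception under TMM scaling, beside 22 of 25 sarcomere and 29 of 29 calcium and ion channel genes (medians -1.71 and -1.99). All 49 tested Mrpl genes, of the large subunit, fell with a median log2 fold change of -1.37, and all 29 Mrps genes, of the small subunit, fell with a median of -1.29 (camera, adjusted p = 4.08e-14 and 7.56e-10). Neither held with an estimated correlation (adjusted p = 0.561 for both). Their smallest falls, -0.45 and -0.76, exceeded the scaling shift of 0.41. Of 14 Timm genes, of the import machinery of the inner membrane, 13 fell (median -1.15), and of 11 Coq genes, of coenzyme Q synthesis, 10 fell (median -1.77). Camera called both (adjusted p = 0.000249 and 0.00645), neither with an estimated correlation (adjusted p = 0.561 for both).

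Toll-like receptors, sensors of microbial and damage products, rose in 9 of 10 cases with a median of 2.06 (camera, adjusted p = 0.00537, and 0.561 with an estimated correlation), beside 14 of 19 macrophage markers (median 2.52). Tlr2 had a log2 fold change of 1.86. Of 43 genes starting with Il, interleukins and their receptors, 27 rose and 3 fell, and of 16 Tnfrsf genes, receptors of the tumour necrosis factor family, 11 rose and 1 fell. Camera called both (adjusted p = 0.00245 and 0.00645), neither with an estimated correlation (adjusted p = 0.561 and 0.36). Of 171 families with at least 10 tested members, 34 were called, 16 up and 18 down, and 0 held with an estimated correlation.

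Other splits of the libraries into groups of the same sizes were fitted the same way. For the 12-library count, the real split with 10366 called genes was 1 of 100 splits that large and the highest other gave 0. For replicates 3 to 6, 1 of 35 splits gave as many as the real 11281 and the highest other gave 0. Chance can be excluded for both only if replicates 3 to 6 are separate samples. That is not known for sham and is argued against for MI by the level lung signal. Chance is therefore not excluded between animals. With replicates 3 to 6 counted once, 10 splits exist, too few for a share under 0.05, and the real count was 8060 against 0 for the highest other. For lists called by camera, 29 of 100 splits gave at least the real 20 and the highest other gave 22. The others that large exchanged 1 or 2 libraries and so kept most of the contrast. Splits that exchanged 3, with 3 sham and 3 MI libraries on each side, still gave 0 to 17 lists with 0 called genes. The rule set beforehand asked for a share under 0.05, so chance is not excluded for the list calls at the preset correlation.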
